A study of Mus musculus with 8 samples.

How the data were processed

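Gene expression was measured in the ventral prostate of FVB mice aged 20 weeks. Per the labels' protocols, total RNA was purified with Trizol and then an RNeasy column, labelled with biotin and hybridised to Affymetrix mouse arrays, 1 array per sample. The labels give 4 wild type samples described as normal and 4 transgenic samples described as mouse prostatic intraepithelial neoplasia, and the series design names an active allele of p110 beta, a catalytic subunit of PI3-kinase, as the transgene. The labels number the samples 1 to 4 in each group. Nothing in them says whether each array came from a separate animal, so p-values measure the spread between these samples, which may be partly technical.

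The deposited values are on a log2 scale and were made with RMA per the submitters' processing notes, with no version given. RMA corrects background, applies quantile normalization and summarises the probes of a probe set, so a difference that affected all transcripts alike would be removed by it. The table held 22690 probe sets, of which 64 control probe sets were left out of the tests, and every column of values was used. The number of arrays limits the precision. Array medians lay between 5.40 and 5.51 on the log2 scale, and the SD of all values of an array lay between 1.92 and 2.10. No 2 arrays were copies of each other: the highest correlation between arrays was 0.996, and at most 40 of the 22626 probe sets tested had identical values on a pair of arrays of the same group.

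Probe sets were named from the platform annotation given with the series, with symbols looked up by gene identifier in the RefSeq gene table of assembly GRCm38.p6, which was used for names only. In that annotation 20380 probe sets had 1 symbol, 691 had several and 1555 had none, and 29 of those with 1 symbol had no entry in the RefSeq table and kept their symbol. Each of 12393 genes was represented by the probe set with exactly 1 symbol and the highest mean over the arrays. The transgene's own gene Pik3cb was named by no probe set used and is not analysed here.

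All probe sets were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, transgenic against wild type), with Benjamini-Hochberg adjustment over the 22626 probe sets and a threshold of 0.05. Fold changes are transgenic minus wild type on the log2 scale. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 35 lists, with an estimated correlation, ranks and fry as alternatives. Counts of list members past the threshold are given over all probe sets tested and adjusted over the list alone. The distance between groups was tested by an exact permutation test over the 70 assignments of arrays to groups, which cannot give a two-sided p below 0.0286. The lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a text below says otherwise.

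The rule names Pik3ca, Pik3cd, Pik3cg and Pik3r1 whatever their values, then, among genes past the threshold whose groups did not overlap, the 12 with the largest and the 12 with the smallest fold change, leaving out unnamed gene models. It then takes up to 4 members past the threshold of each pathway or quality list and up to 2 of each cell type list, by size of change, or the member with the smallest p where none passed. Of the 103 genes this gave, 88 passed the threshold; the text prints a part of them, and other list members it prints were chosen after their values were seen.

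Alternatives were quantile and cyclic loess normalization of the deposited values, leaving out the dimmest 40% or 60% of probe sets, a mean-variance trend with a robust prior, array weights, the mean of all probe sets of a gene, leaving out probe sets marked as shared between transcripts, the replicate number as a block, a stromal score as a covariate and leaving out each array. The stromal score of an array is the mean of the gene-centred log2 values of the smooth muscle and fibroblast marker lists. Thresholds of 0.01 and of 1.5-fold and 2-fold were also applied to the counts.

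The fit was tested on simulated data with the real means and SDs of the 22626 probe sets and 200 changed genes, for transgenic against wild type. It recovered 47.8% of genes changed by 0.5 on the log2 scale, 85.1% of those changed by 1 and 100% of those changed by 2, with 3 false calls among 167. A further list of 20 genes was shifted by 0.5, and the 167 calls include its called members. The simulated genes varied independently, so 0 of 20 unchanged lists being called there says nothing about lists of correlated genes.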

Results

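Expression in the ventral prostate was compared between 4 wild type samples and 4 samples from mice carrying an active allele of the PI3-kinase subunit p110 beta, which the labels describe as having prostatic intraepithelial neoplasia. The question was which genes differ between normal prostate and this lesion at 20 weeks. The arrays measured 12393 named genes as log2 RMA values.

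Transgenic prostates differed widely from wild type. In the limma fit 742 genes rose and 617 fell, together 1359 genes, and 204 of the first and 89 of the second changed by more than 2-fold. The mean distance between arrays of different groups exceeded that within groups by 19.4 on the log2 scale, with 52.3 between and 32.9 within (exact permutation p = 0.0286, the smallest the 8 arrays can give). The groups did not overlap for 16.3% of genes, where chance gives 2.86%. With the stromal score as a covariate the counts were 322 higher and 265 lower, while with array weights 1068 genes were lower and with array spread as a covariate 984. Leaving out transgenic array 2 gave 493 higher and 361 lower genes, and the lower genes numbered 396 without wild type array 3 and 379 without transgenic array 3 or 4.

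The 12 genes with the largest rises under the naming rule encode proteins of several kinds. Tff3, a trefoil peptide of mucus-producing epithelia, went from 6.49 ± 0.62 to 13.58 ± 0.17 (SD, n = 4 each), a 136-fold rise with an adjusted p of 3.15e-08. Sval1 rose 132-fold, from 4.23 ± 0.22 to 11.27 ± 0.55 (SD, n = 4 each). The serum amyloid genes Saa1 and Saa2, which encode acute phase proteins, rose 96.2-fold and 37.7-fold, and both Saa1 probe sets passed the threshold. The Saa2 probe set and the Saa1 probe set not used for the fold are marked as shared between transcripts. The rises of Saa1 and Saa2 may thus not be independent. Fcgbp, which encodes a protein of mucus, rose 33.1-fold, from 6.95 ± 0.51 to 11.99 ± 0.15 (SD, n = 4 each). Rep15 rose 20.4-fold, Hsd11b2, the enzyme that inactivates glucocorticoids, 19.3-fold, and the secreted phospholipase gene Pla2g10 17.6-fold. Tesc, Lypd8, Serpinb1a and Fxyd4 rose between 10.1-fold and 13.3-fold. For 6 of the 12, Sval1, Saa2, Rep15, Hsd11b2, Pla2g10 and Lypd8, the wild type mean lay below the median of every array, where background can set the value, so their folds are approximate and their order is not read.

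Among the genes that fell, Scgb2b27, of the secretoglobin family, went from 11.17 ± 0.58 to 6.74 ± 0.39 (SD, n = 4 each), a level 21.5-fold higher in wild type (adjusted p = 1.94e-06). The family did not fall as a whole. A probe set named for both Scgb2b7 and Scgb2b20, not used for any gene, rose by 4.86 in limma (adjusted p = 9.82e-06). The beta defensin gene Defb10 was 6.49-fold higher in wild type, and Mgll, which encodes monoacylglycerol lipase, 6.11-fold. Ccnd2, encoding cyclin D2, was 5.57-fold higher in wild type, and all 7 of its probe sets fell. The retinoic acid binding protein gene Crabp1 and Id4, an inhibitor of basic helix-loop-helix factors, fell by 2.24 and 2.22 on the log2 scale. Aass and Cbs, of lysine and homocysteine metabolism, fell by 2.11 and 1.94, Pik3c2g, a class II PI3-kinase, by 2.11 and the metallothionein gene Mt2 by 2.01, and Derl3 was 4.29-fold higher in wild type. Ibsp, at 6.67 ± 2.15 in wild type and 3.25 ± 0.27 in transgenic samples (SD, n = 4 each), missed the threshold without wild type array 3 (adjusted p = 0.0613) or transgenic array 2 (adjusted p = 0.0554), and its other probe set, at -0.77, did not pass. Ibsp also missed the threshold with a mean-variance trend and robust prior (adjusted p = 0.0873). It was at 3.68 in wild type array 2, and leaving out each array gave log2 fold changes from -4.43 to -2.73. The transgenic means of Ibsp, Defb10, Crabp1 and Aass lay below the median of every array, so these 4 falls are approximate too.

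**Figure D1:**
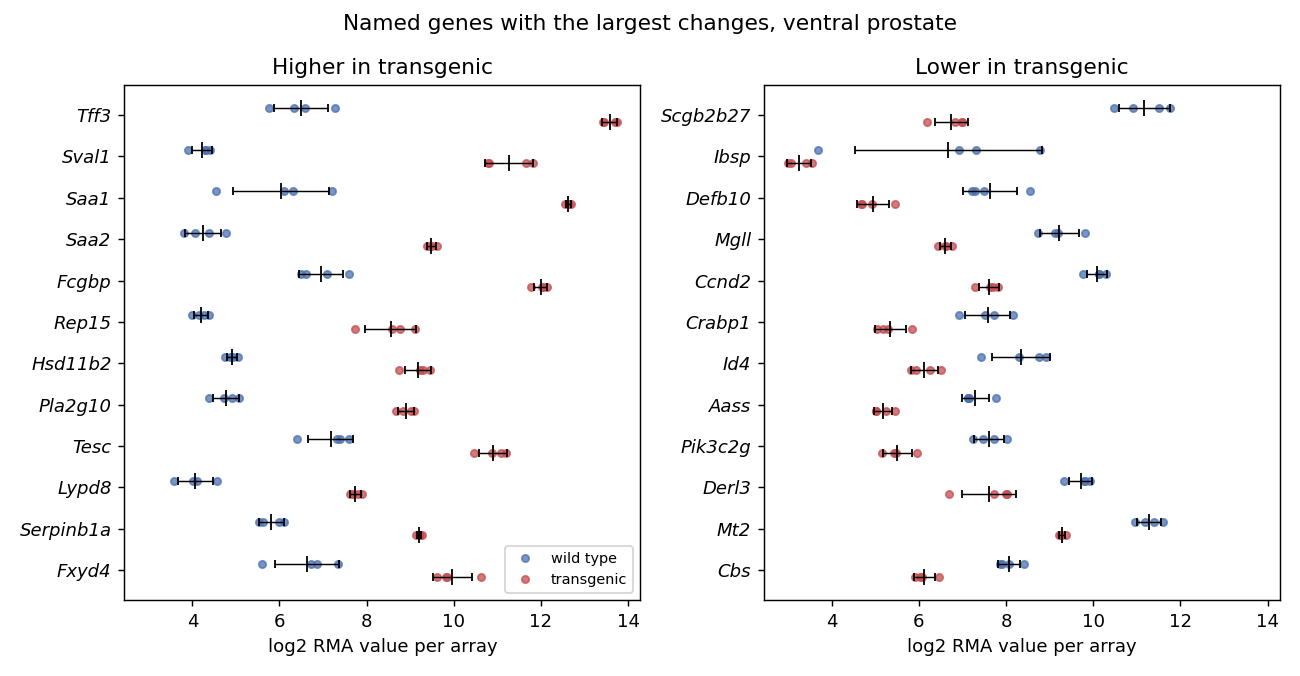
Log2 RMA values per array (horizontal axis) of the 12 genes that rose most and the 12 that fell most under the naming rule, with wild type arrays in blue and transgenic arrays in red, and the black marks giving the mean and SD of 4 arrays. The groups do not overlap for any gene shown, and the means of Tff3 are 6.49 in wild type and 13.58 in transgenic samples.

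Of the 35 gene lists, 12 passed camera with the preset correlation, 7 higher and 5 lower in transgenic samples. With an estimated correlation 2 passed, glycolysis and luminal epithelial markers, and 10 did not. Of the 35 splits of the 8 arrays into 4 and 4, 5 brought 12 or more lists past the threshold, the real one included. The number of lists is thus not larger than other splits can give. Those others kept most arrays of a group together, so they hold a part of the group difference.

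Glycolysis genes rose as a group. Of 15 measured members, 11 rose, 1 fell and 3 did not pass, with a median log2 fold change of 0.81 (camera adjusted p = 2.42e-12; adjusted p = 0.0253 with an estimated correlation), and adjusted over the list alone 12 rose and 1 fell. Hk2, encoding hexokinase 2, went from 8.08 ± 0.28 to 9.27 ± 0.23 and the glucose transporter gene Slc2a1 from 7.24 ± 0.20 to 8.34 ± 0.12 (SD, n = 4 each). Aldoc rose by 1.08 and Ldha, encoding a lactate dehydrogenase subunit, by 0.93, while the phosphofructokinase gene Pfkm fell by 0.44. A second Aldoc probe set, at -0.06, did not pass. Of 15 HIF-1 induced genes outside glycolysis 4 rose, 0 fell and 11 did not pass (6 and 0 adjusted over the list alone), among them Higd1a by 1.52, Bnip3 by 1.03 and Pdk1, encoding a kinase that inhibits pyruvate dehydrogenase, by 0.86. That list passed camera (adjusted p = 0.00723), with adjusted p = 0.323 with an estimated correlation.

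Among 17 genes of cholesterol synthesis, 8 rose, 0 fell and 9 did not pass, and 10 rose adjusted over the list alone. Sqle, encoding squalene epoxidase, rose by 1.46, Idi1 by 1.35 and Nsdhl by 0.87. Cyp51 missed the threshold without wild type array 3 (adjusted p = 0.0536) or transgenic array 3 (adjusted p = 0.0504), and Dhcr7 without wild type array 3 (adjusted p = 0.0625). The list median was 0.42 (camera adjusted p = 4.54e-07; adjusted p = 0.247 with an estimated correlation). Of 14 genes of fatty acid synthesis, 1 rose, Acly by 0.49, and 1 fell, Scd1 by 0.67, with 12 not passing (1 and 2 adjusted over the list alone) and a list adjusted p of 0.408. Acly missed the threshold under quantile normalization (adjusted p = 0.0515).

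Luminal epithelial markers rose as a group. Of 10 luminal markers 6 rose, 0 fell and 4 did not pass, with a median of 0.50 and 6 higher adjusted over the list alone (camera adjusted p = 4.28e-06; adjusted p = 0.0316 with an estimated correlation). Elf3 went from 6.78 ± 0.15 to 8.04 ± 0.09 and Cd24a from 11.24 ± 0.17 to 12.43 ± 0.15 (SD, n = 4 each). Of 11 basal markers 0 rose, 5 fell and 6 did not pass, and 7 fell adjusted over the list alone. The basal keratin genes Krt15 and Krt5 fell by 1.32 and 1.22 and Trp63, encoding the basal cell factor p63, by 0.70. The basal list had a median of -0.34 (camera adjusted p = 0.000251; adjusted p = 0.115 with an estimated correlation).

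Some markers of stroma fell. Of 12 smooth muscle markers 3 fell, 9 did not pass and 0 rose (5 fell adjusted over the list alone), including Pcp4 by 1.20 and Smtn by 0.70. Of 12 fibroblast markers 2 fell, 10 did not pass and 0 rose (6 fell adjusted over the list alone), with Dcn, encoding decorin, at 11.01 ± 0.28 in wild type and 9.87 ± 0.04 in transgenic samples (SD, n = 4 each). Of 20 extracellular matrix genes 3 fell, 17 did not pass and 0 rose (4 fell adjusted over the list alone), the collagen genes Col4a2, Col4a1 and Col6a3. The lists passed camera with adjusted p of 0.0013, 0.000357 and 0.000864, against adjusted p = 0.508, adjusted p = 0.570 and adjusted p = 0.570 with an estimated correlation. Pdgfra, 1 of the 2 fibroblast markers, missed the threshold without any one of 6 arrays (all but wild type arrays 1 and 4; adjusted p up to 0.129), with replicate number as a block (adjusted p = 0.0549) and with the mean of its probe sets (adjusted p = 0.0529), and its other probe set, at -0.14, did not pass. The stromal score was 0.28 ± 0.42 in wild type and -0.28 ± 0.12 in transgenic samples (SD, n = 4 each; exact permutation p = 0.0286, or 0.0857 adjusted over 3 array measures). This score is built from the smooth muscle and fibroblast lists. The extracellular matrix list shares Col1a1, Col1a2 and Col3a1 with the fibroblast list, so its change under the score is partly built in. With the score as a covariate, the extracellular matrix and fibroblast lists turned to higher without passing (adjusted p = 0.436 and 0.496). Smooth muscle was at adjusted p = 0.921. Col4a2, Col4a1 and Col6a3 lost their calls (adjusted p = 0.392, adjusted p = 0.245 and adjusted p = 0.0702). Their log2 fold changes were -0.34, -0.50 and -0.69 with the score, against -0.65, -0.65 and -0.59 without it. The luminal and basal lists and the changed genes above differ between the same samples as this score, and with the score as a covariate 30 of the 103 named genes lost their call. Of these, 28 kept over 50% of their fold, with a median ratio over all 30 of 0.93, and standard errors changed by a median factor of 1.48. The exceptions were Igfbp5, at -0.78 ± 0.22 (SE) without the score and -0.09 ± 0.15 with it, and the fibroblast gene Pdgfra, at -0.74 ± 0.20 and -0.19 ± 0.19. The log2 fold change of Msmb was -1.72 ± 0.32 (SE) without the score and -1.72 ± 0.49 with it, and that of Krt15 -1.32 ± 0.26 and -1.18 ± 0.40.

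**Figure D2:**
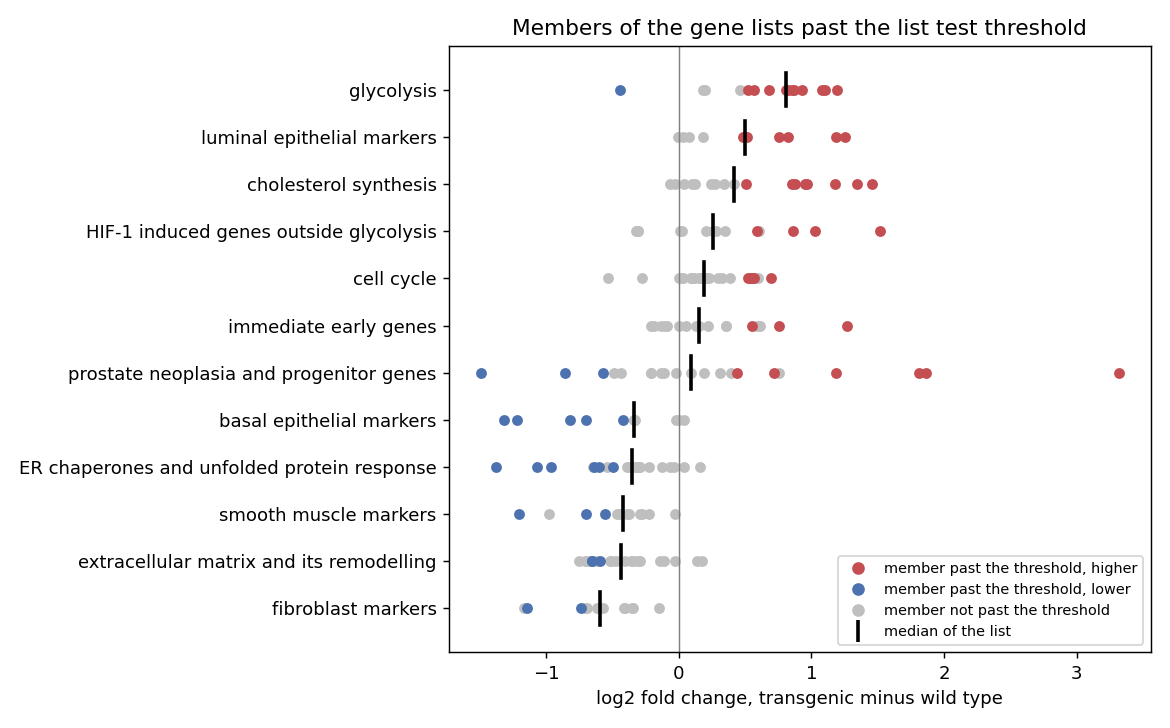
Log2 fold change, transgenic minus wild type (horizontal axis), of each measured member of the 12 gene lists past the camera threshold with a preset correlation (vertical axis). Red and blue points are members past the limma threshold, higher or lower, grey points are the others, and black bars are list medians, from 0.81 for glycolysis to -0.59 for fibroblast markers.

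Genes of prostate function showed mixed changes. Of 11 secretory protein genes 1 rose, 4 fell and 6 did not pass (3 and 6 adjusted over the list alone), with Msmb at 13.38 ± 0.22 against 11.66 ± 0.83 and the probasin gene Pbsn at 12.85 ± 0.35 against 11.57 ± 0.45, wild type against transgenic (SD, n = 4 each), while Klk1b27 rose by 0.70. The wild type and transgenic means of Klk1b27, 4.00 and 4.70, lay below the median of every array, so its rise is approximate. Azgp1, among the 4 that fell, missed the threshold without any one of 5 arrays (adjusted p up to 0.0916). These were all arrays but wild type arrays 1 and 2 and transgenic array 4. Of 19 androgen-induced genes 1 rose, 5 fell and 13 did not pass (3 and 6 adjusted over the list alone), where Gnmt fell by 1.58, Hpgd by 0.92 and Tmprss2, a transmembrane protease gene, rose by 0.97. Homer2, among the 5 that fell, missed the threshold without any one of 6 arrays (all but wild type arrays 3 and 4; adjusted p up to 0.132). Neither list passed camera (adjusted p = 0.156 and 0.113).

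Of 21 genes linked to prostate neoplasia and progenitor cells in mice, 6 rose, 3 fell and 12 did not pass (7 and 3 adjusted over the list alone). Wfdc2 rose 9.96-fold, Psca, prostate stem cell antigen, 3.64-fold and Sox4 3.51-fold, while Aldh1a1 fell by 1.49 on the log2 scale. The 6 Sox4 probe sets ranged from 0.46 to 1.81 on the log2 scale, with 5 past the threshold, and the fold given is from the highest. The list had an adjusted p of 0.0392 (adjusted p = 0.247 with an estimated correlation), and it was lost without wild type array 1 (0.0511) or 4 (0.0720) and without transgenic array 1 (0.0541) or 3 (0.0653). Of 29 cell cycle genes 5 rose, 0 fell and 24 did not pass (7 rose and 1 fell adjusted over the list alone). Among those that rose were Mcm6 by 0.70 and the proliferation marker gene Mki67 by 0.55. The wild type mean of Mcm6, 4.83, and both means of Mki67, 4.33 and 4.89, lay below the median of every array, so these rises are approximate. Mki67 missed the threshold with the stromal score as a covariate (adjusted p = 0.242). Of the 5, Cdk1 missed the threshold without any one of 6 arrays (all but wild type arrays 3 and 4; adjusted p up to 0.113) and Pcna without wild type array 3 or 4 or transgenic array 2 or 3 (adjusted p up to 0.102). That list passed camera (adjusted p = 0.000152), with adjusted p = 0.570 with an estimated correlation.

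Some genes of the endoplasmic reticulum fell. Of 20 chaperone and unfolded protein response genes 6 fell, 14 did not pass and 0 rose, and 11 fell adjusted over the list alone. Herpud1 went from 11.14 ± 0.19 to 10.07 ± 0.19 (SD, n = 4 each), Creld2 fell by 1.37 and Sdf2l1 by 0.96. The list median was -0.35 (camera adjusted p = 4.96e-05; adjusted p = 0.442 with an estimated correlation).

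Of 17 immediate early genes, listed as a sign of tissue handling, 3 rose and 14 did not pass, over all probe sets and adjusted over the list alone (camera adjusted p = 0.0332; adjusted p = 0.570 with an estimated correlation). Jun rose by 0.76, and missed the threshold without wild type arrays 1 and 4 (adjusted p = 0.0868). Dusp1, up by 1.27, missed it without any one of 6 arrays (all but wild type array 2 and transgenic array 1; adjusted p up to 0.0903). Btg2, up by 0.55, missed it without any one of 5 arrays (all but wild type array 2 and transgenic arrays 1 and 3; adjusted p up to 0.104), under quantile (adjusted p = 0.0991) and cyclic loess normalization (adjusted p = 0.0688) and with replicate number as a block (adjusted p = 0.0546). Dusp1 was at 7.59 in wild type array 2 and between 5.90 and 5.94 in the other wild type arrays. The list was lost without wild type array 1, 3 or 4 or transgenic array 4, with adjusted p from 0.0511 to 0.138. As a sign of RNA quality, the 3 prime minus 5 prime log2 difference of the Gapdh and beta actin control probe sets was 1.47 ± 0.09 in wild type and 1.12 ± 0.19 in transgenic samples (SD, n = 4 each; exact permutation p = 0.0571, or 0.0857 adjusted over 3 array measures).

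Markers of immune cells gave few changes. Of 16 macrophage and monocyte markers 1 rose, Mrc1, the mannose receptor gene, from 6.44 ± 0.56 to 8.71 ± 0.24 (SD, n = 4 each; adjusted p = 0.000106), which is also the count adjusted over the list alone. Of 8 genes of antigen presentation by MHC class II, 1 rose, Ctss by 0.90 (1 and 1 lower adjusted over the list alone). No marker of neutrophils, T and NK cells, B and plasma cells or mast cells passed in limma, over all probe sets or adjusted over the list alone, and of these 42 genes 4 had an unadjusted p under 0.05. Among those also run under the alternatives, Ltf and Prf1 passed with array weights. Their log2 fold changes were -1.32 (adjusted p = 0.0220) and -0.32 (adjusted p = 0.0384). Ltf and Cpa3 passed without wild type array 1, at -1.51 (adjusted p = 0.0164) and -0.38 (adjusted p = 0.0475). The lower group means of Ltf, Prf1, Tnfrsf17 and Cpa3 lay below the median of every array, at 5.17, 4.17, 4.04 and 4.46. Changes near background can be missed, so the lack of calls does not show that these cells were unchanged. Of 17 interferon response genes Oas1a rose by 0.61 and Ifit1 fell by 0.73, the same counts adjusted over the list alone. Of 24 cytokines and chemokines Cxcl10 fell by 0.37, a call lost without any one of 6 arrays and adjusted over the list alone. The wild type and transgenic means of Ifit1, 5.19 and 4.46, and of Cxcl10, 4.41 and 4.04, lay below every array median. Both falls are therefore approximate. These lists had camera adjusted p from 0.276 to 0.821, but with the stromal score as a covariate the macrophage list turned to higher and passed (adjusted p = 0.000531). The median and the test of the interferon list were positive and its mean negative, and for macrophages the mean was positive and the median and test negative.

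Other cell type lists did not pass. No member of the neuroendocrine, endothelial, adipocyte, skeletal muscle, seminal vesicle or red blood cell lists passed in limma, over all probe sets or adjusted over the list alone, and of these 54 genes 4 had an unadjusted p under 0.05. Acta1, of the skeletal muscle list, passed with array weights (adjusted p = 0.00445), without wild type array 1 (adjusted p = 0.0117) and without wild type arrays 1 and 4 (adjusted p = 0.00717), at log2 fold changes of -0.89, -0.81 and -0.98. Upk1a, a urothelial gene, fell by 0.96, and among nerve and Schwann cell markers Ncam1 fell by 1.54 and Mbp rose by 0.48, the same counts adjusted over the list alone. Of 6 Ncam1 probe sets 2 fell and the others ranged up to 0.18, and of 8 Mbp probe sets 2 rose, a call lost under quantile normalization (adjusted p = 0.0916), cyclic loess (adjusted p = 0.0739), with the mean of its probe sets (adjusted p = 0.559) and without any one of 5 arrays. These lists had camera adjusted p from 0.169 to 0.847.

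Few genes of the PI3-kinase pathway changed in expression. Pik3ca was at 7.67 ± 0.13 and 7.71 ± 0.04, Pik3cd at 4.49 ± 0.12 and 4.54 ± 0.07, Pik3cg at 4.98 ± 0.25 and 4.89 ± 0.14 and Pik3r1 at 5.66 ± 0.49 and 6.11 ± 0.26 in wild type and transgenic samples (SD, n = 4 each), with adjusted p of 0.865, 0.856, 0.786 and 0.275. With array weights Pik3r1 passed, at a log2 fold change of 0.67 (adjusted p = 0.0349). Of 18 pathway components 1 passed, the insulin receptor substrate gene Irs1, which fell by 0.89, also adjusted over the list alone. Of 21 FOXO-induced genes 4 rose, 2 fell and 15 did not pass (8 and 4 adjusted over the list alone), with Klf4, a transcription factor gene, rising 6.67-fold and Cited2 and Klf15 falling by 0.89 and 0.74. Sod2, among the 4 that rose, missed the threshold without any one of 5 arrays (all but wild type arrays 1 and 2 and transgenic array 1; adjusted p up to 0.114). Of 13 cell cycle inhibitors and senescence-linked genes 1 rose, Glb1 by 0.61, and 2 fell, including Cdkn2c by 0.65, the same counts adjusted over the list alone, and Igfbp5, the other that fell, missed the threshold without any one of 7 arrays (all but wild type array 1; adjusted p up to 0.123). No gene of 20 in ribosome biogenesis passed in limma, over all probe sets or adjusted over the list alone, and 4 had an unadjusted p under 0.05. Bop1 passed with array weights, at -0.43 (adjusted p = 0.0177), and without transgenic array 1, at -0.42 (adjusted p = 0.0480). Its only probe set, at -0.36, also passed where genes were tested by the mean of their probe sets (adjusted p = 0.0454). It passed without the dimmest 60% of probe sets as well (adjusted p = 0.0463). In both cases its fold was that of the main fit, and the adjustment was over fewer tests. These 4 lists had camera adjusted p of 0.658, 0.276, 0.580 and 0.276, and the ribosome list passed without wild type array 4 (0.0455).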

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

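Tests of array spread, of luminal cells and of macrophages were chosen after the results were seen, and the others were set before. Single arrays stood apart from the other 3 of their group in 14 of 276 groups of values examined, where chance gives about 13.8, so the flags as a set are no more than chance. The gap of the array to its nearest neighbour, as a share of the range of its group, was 0.976 for Dusp1 and 0.911 for the immediate early score in wild type array 2, which was at 0.23 against -0.27 to -0.23. It was 0.936 for Aass and 0.905 for the red blood cell score in wild type array 1. In wild type array 2 it was also 0.943 for Glb1 and 0.848 for Upk1a. In transgenic array 4 it was 0.855 for Glb1, 0.884 for Hpgd, 0.860 for Sdf2l1 and 0.847 for Cxcl10. In transgenic array 3 it was 0.874 for Elf3 and 0.886 for Alas2, and in transgenic array 1 it was 0.852 for the HIF-1 score and 0.833 for the ribosome biogenesis score. Among 2246 probe sets with no gene name or several, which the gene counts and lists above do not use, 122 were higher and 77 lower in transgenic samples by limma.

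The number of genes past the threshold was exceeded or equalled by 1 of the 35 splits of the arrays, the real one. That split gave 1359 genes against at most 1 in any other split. A share of 1 in 35 is the smallest these splits can give. Every other split mixes wild type and transgenic arrays, so a difference between those groups widens the spread within its sides and lowers its count. The real count was thus the largest, but this test cannot exclude chance for it. For gene lists 5 of the 35 splits reached the real number of 12 and the highest other gave 18. The other splits that reached 12 put 3 arrays of 1 group with 1 of the other, so they keep a part of the group difference. Splits with equal numbers of both groups on each side gave at most 11. This count therefore does not exclude chance for the number of lists, and does not show it either. The 4 splits that put wild type array 1 with 3 transgenic arrays gave 18, 16, 15 and 9 lists, and each called 0 genes.

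Glycolysis genes were higher in transgenic samples, and cell content was weighed against it. With the stromal score as a covariate the list median was 0.717, against 0.811 without it, and the list passed (adjusted p = 1.19e-10), which argues against less stroma as the whole cause. Under cyclic loess of the RMA values it was 0.765, which argues only against scaling differences left after RMA that cyclic loess can remove. A bias that both methods share would not show in this test. More luminal cells stay open: the per-array glycolysis median minus the luminal median was higher by 0.180 in transgenic samples (exact permutation p = 0.143), and 2 of the 4 transgenic arrays lay above all wild type arrays. A change of glycolysis within luminal cells, from the transgene, may also contribute and was not tested.

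Arrays of one group spread along the second principal component, which held 21.8% of the variance against 53.5% for the first. Within groups it followed the SD of all values of an array (r = 0.975, rho = 0.905, exact permutation p = 0.00868 and 0.0156, or 0.0260 and 0.0469 adjusted over 3 measures). Without the 2 arrays farthest from the median r was 0.952. This met the mark set for array spread as the cause, r of 0.8 or more with p under 0.05. Yet quantile normalization, which gave each array an SD of 2.02, left a second component with 19.0% of the variance. That one correlated with the original at 0.991, which argues against unequal spread itself as the whole cause. Equal SDs do not remove effects on single genes of a technical factor that also changes spread, so such a factor stays open. The stromal score did not follow the component over all arrays (r = -0.021, rho = 0.048, permutation p = 0.988 and 0.948). Its r was -0.439 without 2 arrays, 0.587 within transgenic arrays and -0.121 within wild type arrays. The upper bound of the size of r, 0.762, lies just below the 0.8 set beforehand. That argues against stromal content as the whole cause, while a large part stays open. RNA degradation stays open (r = -0.404, rho = -0.357, permutation p = 0.302 and 0.396; r = -0.563 without 2 arrays), as 8 arrays leave a bound of 0.887. No biological explanation was tested.

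Mrc1 rose by 2.27 in transgenic samples. The 15 other macrophage and monocyte markers had a mean log2 fold change of -0.143, with a 95% interval from -0.539 to 0.252, and with the stromal score as a covariate 0.229 (from -0.048 to 0.505), where Mrc1 was at 2.96. With that score the whole list turned to higher and passed (adjusted p = 0.000531), so some more macrophages stay possible, but both upper bounds lie below 1.13 and 1.48, the Mrc1 change divided by 2, which argues against more macrophages as the whole cause. A single probe set reading another transcript stays open, since 0 other probe sets are named Mrc1. A change of Mrc1 within macrophages or another cell type, linked to the transgene, may also account for it and was not tested.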

How the results depend on the processing

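The covariate of array spread and the fit without wild type arrays 1 and 4 were chosen after seeing the data. The other alternatives were planned, and causes were not tested. Without wild type arrays 1 and 4 the calls of 20 named genes were lost and 1 was gained. Among the losses were Msmb (adjusted p = 0.0557), Krt15 (0.0574), Pcp4 (0.0554), Col6a3 (0.0591), Scd1 (0.0621), Oas1a (0.0844) and Ctss (0.0855). Glycolysis and luminal markers passed in all 23 alternatives run for each, with adjusted p up to 0.0253 and 0.0316. Of the 12 lists past the threshold 10 were lost with the estimated correlation, with adjusted p of 0.323 for HIF-1 induced genes, 0.247 for cholesterol synthesis and neoplasia genes (ranks gave 0.295 for the latter), 0.570 for cell cycle, extracellular matrix, immediate early and fibroblast genes, 0.442 for endoplasmic reticulum, 0.115 for basal and 0.508 for smooth muscle markers (the stromal score gave 0.921 for the latter). Under fry cell cycle, extracellular matrix and fibroblast lists were at 0.130, immediate early genes at 0.184 and smooth muscle at 0.0803, while androgen-induced and skeletal muscle lists passed at 0.00648. With ranks HIF-1 induced genes were at 0.0839. The neoplasia and immediate early lists missed the threshold under quantile (0.118, 0.0524) and cyclic loess normalization (0.124, 0.0595), without the dimmest 40% (0.123, 0.0680) or 60% of probe sets (0.232, 0.145), with array weights (0.0772, 0.0799), with array spread (0.108, 0.0904) and without wild type arrays 1 and 4 (0.106, 0.219), and the neoplasia list without shared probe sets (0.0698). Without the dimmest 60% the cell cycle list was at 0.394 and basal markers at 0.0503; secretory proteins passed at 0.0453 without the dimmest 40% and 0.00158 without 60%. Androgen-induced genes passed with the mean of probe sets (0.0464) and ribosome biogenesis with array spread (0.0436). With the stromal score, built from fibroblast and smooth muscle lists, the extracellular matrix (0.436) and fibroblast (0.496) lists turned to higher without passing, and macrophage markers turned to higher and passed (0.000531); the 30 named genes that lost their call had folds at a median of 0.93 of those without it, with 28 above 50%. That score left 322 genes higher and 265 lower, of which 554 were also called without it, in the same direction. Lower genes numbered 1068 with array weights and 984 with array spread. At 0.01 there were 408 higher and 259 lower, at 1.5-fold 492 and 319, at 2-fold 204 and 89, and as probe sets 1241 and 986. Leaving out each array gave 493 to 820 higher and 361 to 691 lower genes, adjusted p from 0.0244 to 0.0720 for the neoplasia list, 0.000411 to 0.138 for immediate early genes and 0.0455 to 0.637 for ribosome biogenesis, and a distance between groups from 16.9 to 21.8. The distance kept its direction and the smallest p the 8 or 7 arrays allow, also without the dimmest 40% and as 1 minus Pearson correlation. Whether equal replicate numbers pair the arrays is not settled. For numbers 1 to 4 the correlations of deviations were -0.30, 0.22, -0.18 and 0.34, with numbers 2 and 4 over the bound of 0.1. The arrays were treated as unpaired because not all passed it. As a block the replicate numbers gave 599 genes higher and 486 lower, and changed no list's call and 7 named genes' calls. Over all alternatives the 88 named genes past the threshold kept their call in 1610 of 1746 values, lost it in 136 and turned direction in 0, and the other 15 gained a call in 12 of 281. The Pik3cb alternative was not run, and alternatives that left a list under 3 members gave no value. Signal over background was not used here to limit the genes tested, so folds of genes with a group below the array medians are approximate.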

Other observations

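The 4 lists tested here were made after the genes with the largest changes had been seen, from members whose values had not been, and adjusted over 4 lists. They were prompted by and tested in the same arrays, so a list that passed is not independent evidence. The luminal list, the stromal score (0.28 in wild type and -0.28 in transgenic samples) and the 3 prime minus 5 prime difference of control probe sets (1.47 and 1.12) differ between the same samples, and a fit with that score as a covariate was added after seeing the data. Lysosomal genes were higher in transgenic samples: of 29 measured, 14 rose, 1 fell and 14 did not pass. Neu1, encoding a sialidase, rose by 1.54, Ctsa, its protective partner, by 1.11, Manba by 1.06 and Man2b1 by 1.01, while Ctsz fell by 1.05. The lysosomal list passed as higher with both correlations, at a mean of 0.404 (95% interval 0.336 to 0.472, camera adjusted p = 6.26e-11, adjusted p = 0.00453 with an estimated correlation). With the stromal score the mean was 0.367, 6 members rose and 1 fell (camera adjusted p = 2.90e-08; adjusted p = 0.0231 with an estimated correlation), while luminal content and RNA quality were not tested for this list.

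Of 22 goblet cell and mucin genes, chosen because Tff3 and Fcgbp were among the 12 largest rises, 7 rose and 0 fell. They included Fxyd3 by 1.45, Galnt4 by 1.34, Clca1 by 1.29 and Tspan1 by 1.28, with the secretory lineage factor genes Atoh1 by 1.16 and Spdef by 0.68. The wild type means of Atoh1 and Clca1, 4.86 and 4.33, lay below the median of every array, so their rises are approximate. The list mean was 0.413 (95% interval 0.272 to 0.553, camera adjusted p = 9.53e-07, adjusted p = 0.0336 with an estimated correlation). A higher mucous secretory program is a hypothesis that these values leave possible. Luminal content and RNA quality were not tested for this list or for the lists below. In the fit with the stromal score the mean was 0.393 and 4 rose (camera adjusted p = 1.53e-05), but the list missed the threshold with an estimated correlation (adjusted p = 0.0688). The mucin genes Muc1, Muc4 and Muc13, at -0.07, -0.14 and 0.10, did not pass. Nor did, among others, the goblet cell genes Spink4, Zg16, Tff2 and Retnlb, at -0.005, 0.03, 0.04 and 0.20.

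Of 26 amino acid catabolism enzymes, chosen because Aass and Cbs were among the 12 largest falls, 5 fell and 2 rose. Bckdha and Dbt, of branched-chain amino acid breakdown, fell by 0.77 and 0.70, Asl by 0.77 and Fah by 0.60. The mean was -0.218 (95% interval -0.277 to -0.159, camera adjusted p = 0.00561, adjusted p = 0.0336 with an estimated correlation). The list thus passed as lower in this fit, with a small mean. In the fit with the stromal score the mean was -0.213 and 4 fell (camera adjusted p = 0.0135), and the list missed the threshold with an estimated correlation (adjusted p = 0.0688).

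Of 20 acute phase and NF-kB or STAT3 induced genes, chosen because Saa1 and Saa2 rose, 4 rose, among them Bcl3 by 1.44 and Relb by 0.89, and 1 fell, Cp by 0.75. The mean was 0.102 (95% interval -0.088 to 0.293; camera adjusted p = 0.112; adjusted p = 0.453 with an estimated correlation), so the data do not decide whether the group is higher. Adding the stromal score gave a mean of 0.235 (camera adjusted p = 0.00826; adjusted p = 0.190 with an estimated correlation).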
